A study of Mus musculus with 37 samples.

How the data were processed

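Multiplex reverse transcription and TaqMan quantitative PCR were run on 20 to 1000 sorted cells per sample, per the labels, which state 425 mature miRNAs. The deposited values are threshold cycles (Ct values) per assay and run, given to 1 decimal, with 40 where no amplification was seen. A lower Ct means more RNA, and 1 cycle is 1 log2 unit if PCR efficiency is 100 percent, a 2-fold change per cycle. The software, the threshold setting and any normalization by the authors are not given in the sources used here. Each of the 37 runs held 459 assays with 457 distinct names, because miR-96 and miR-337 have a pair of assays each. The panel as deposited held no control small RNA. A nameless extra value of 38.5 in KSL-RbTKO replicate 2 was left out.

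The runs fell into 12 groups by their labels, and KSL was split by strain. NSPC-Adult replicates 2 and 3, labelled C57/Bl7 and C57/Bl8, stayed in 1 group with replicate 1. Within each group the spread of Ct differences between runs was checked. MuSC runs 1 and 2 differed by an SD of 0.156 over 60 assays below Ct 32, and runs 3 and 4 by 0.211 over 42, so each pair was averaged as 1 sample. Between the MuSC samples the SD was 1.17 to 1.28 in 4 pairs of runs, and within the other groups 0.324 to 1.09 in 35 pairs. An assay was detected in a run below Ct 35. Between 61 and 143 assays were detected per run, and this number limits the precision.

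For each comparison, Ct was turned into a log2 level by centring each sample on its mean Ct over the assays detected in every run compared. Levels below the lowest level measurable in all samples were set to that common floor. An assay was tested if every run of at least 1 group detected it. Groups were compared with limma 3.58.1 in R 4.3.3 (jsonlite 2.0.0 read the labels), by its moderated two-sided test with Benjamini-Hochberg adjustment within each comparison at 0.05. A difference against a group in which no run detected the assay, or every run lay at the floor, is a bound. Groups held at the floor have no spread of their own, so their standard errors are understated. After the counts had been seen, values were rounded to 8 decimals and assays at a constant value were counted as not called, because residues of arithmetic had passed as spread. This changed 5 counts, and the fit without it is among the alternatives.

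The 13 comparisons were 9 between pairs of groups, 3 between a tissue and the other tissues over the means of the normal groups (each tissue set against the mean of the other tissues, so that these 3 differences of an assay sum to 0), and the difference between the blood and the muscle step. Lists were tested with camera, with a preset correlation of 0.01 and then with an estimated one, adjusted over the lists with at least 3 tested assays. The 23 lists, covering tissues, cell type markers, genomic clusters and families, were fixed before the data were examined, as were the groups, the comparisons and most alternatives. Assays called in both the muscle and the blood step were counted against chance with Fisher's exact test and followed as a list through other comparisons.

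Assays were named by a rule: the 10 largest rises and 10 largest falls among calls whose groups did not overlap, so that every sample of 1 group lay above every sample of the other. For tissues, strain and the difference between steps 5 each were named. For the difference between steps overlap was not asked, and calls were named by size alone. To these came up to 3 members of each list described, by adjusted p, and tested members of the tissue lists in the tissue comparisons, of which the text gives a part. The 2 shared falls of the muscle and blood steps, further members of lists, an assay under another control and second assays of a named miRNA were named after their values were seen.

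Sample numbers were checked for pairing by correlating residuals across assays between groups. In LT-HSC against MLL-LSC the 3 pairs correlated at 0.13 to 0.312, each best with its own number. In each of the other 5 comparisons checked at most 1 pair correlated best with its own number. The alternatives were detection limits of Ct 32 and Ct 38, quantile normalization, no scaling, other centrings, no common floor, all assays tested, all groups in 1 fit, a 2-fold filter, a block for the replicate number, other KSL controls and leaving out each sample. Where leaving out a sample left a group with 1, that sample was assumed to vary like the other groups. Calls were also recounted over other splits of the samples. The method was tested on simulated data, 20 sets per comparison with 40 changed assays of 459. Among the changed assays that passed the detection filter, changes of 2 log2 units were recovered in 73.3% (LT-HSC against KSL) to 96.9% (KSL-ETO). None had the wrong direction, and 1.88% to 9.16% of calls were false, most for KSL-RbTKO. The simulated noise had 1 SD for all assays of a comparison, so these shares do not cover assays with a wider spread.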

Results

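Mature microRNAs (miRNAs) were measured by TaqMan quantitative PCR in 37 runs of mouse stem and progenitor cells from muscle, blood and brain, and of leukaemic and mutant blood cells. Each run gave a threshold cycle (Ct) for 459 assays. Muscle had 4 runs of sorted quiescent satellite cells (MuSC) and 4 of myoblasts, the proliferating committed progenitors of limb muscle. Normal marrow gave 4 runs of long-term blood stem cells (LT-HSC) and 5 of Kit+ Sca-1+ lineage-negative progenitors (KSL), 3 from C57/Bl6 mice (KSL-B6) and 2 from mice of mixed strain (KSL-Mixed). The same gate was sorted from AML-ETO9a transgenic mice (KSL-ETO, 3 runs) and from mice without the Rb family (KSL-RbTKO, 2 runs). Kit+ leukaemia stem cells (MLL-LSC) and Kit- leukaemia cells (MLL-Prog) carrying MLL-AF10 had 3 runs each. Neural cells were isolated at birth (NSPC-P0), expanded from those isolates as neurospheres (NSPC-P0-Exp) or grown as neurospheres from adult mice (NSPC-Adult), with 3 runs each. MuSC runs 1 and 2 were near-identical repeats, as were runs 3 and 4, so each pair counted as 1 sample and 35 samples remained.

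Between 61 and 143 assays were detected in a run, and this number limits the precision. KSL-RbTKO had 61 to 65, MuSC 65 to 90 and LT-HSC 73 to 96, against 98 to 143 in the other groups. Values below are log2 differences ± standard error, with 1 log2 unit for 1 cycle after scaling each run. They read "at least" or "or lower" where every run of a group missed the assay or lay at the lowest level common to the runs. Members of a list are assays, so a miRNA with a pair of assays counts as 2. The assays hsa-miR-516-3p, hsa-miR-520e, hsa-miR-520h, hsa-miR-522 and hsa-miR-525 target a cluster known from primates alone, and the source of their signal was not established. The labels do not say that replicates were separate animals or cultures, so each p measures the spread between these samples.

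**Figure D1:**
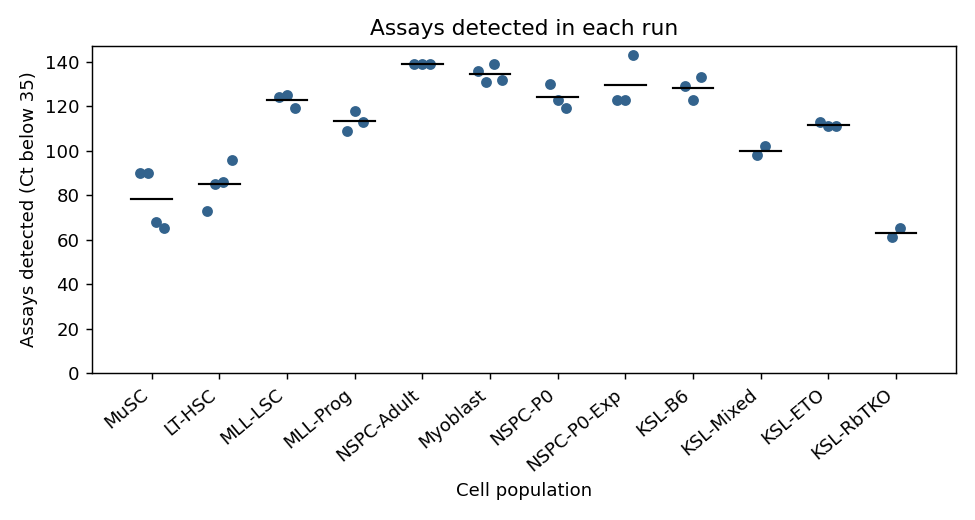
Number of the 459 assays detected (Ct below 35) in each run, by cell population; each point is a run and each bar the mean of its group. Runs of MuSC, LT-HSC and KSL-RbTKO lie between 61 and 96, and all other runs between 98 and 143.

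The step from quiescent muscle stem cells to myoblasts raised the list called here the miR-17 family. The list holds miRNAs of clusters transcribed under the cell cycle regulators Myc and E2F, miR-19 and miR-92 among them. It thus covers more than 1 family by sequence. Of the 13 measured members of this list 11 rose, and 11 when adjusted over the list alone (camera adjusted p = 0.00954, and adjusted p = 0.179 with an estimated correlation). miR-93 rose by at least 8.17 ± 0.15 and mmu-miR-106a by at least 6.24 ± 0.16 (n = 4 myoblast and 2 MuSC samples), while miR-20 rose by 7.23 ± 1.29. Both assays of miR-31 rose most, by at least 11.34 ± 0.14 and at least 9.57 ± 0.18. miR-206, a skeletal muscle miRNA, rose by 4.99 ± 0.31, from Ct 28.85 ± 0.141 (SD, n = 2) to 21.15 ± 0.592 (SD, n = 4). miR-222, which targets Kit and Cdkn1b, rose by 5.14 ± 0.18, miR-149 by 5.23 ± 0.66 and miR-186 by at least 5.54 ± 0.14.

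All 5 measured members of the imprinted Dlk1-Dio3 cluster were lower in myoblasts, and 5 when adjusted over the list alone (camera adjusted p = 8.31e-05, and adjusted p = 0.179 with an estimated correlation). They included miR-381 at -5.32 ± 0.41, miR-379 at -3.83 ± 0.53 or lower, miR-134 at -3.68 ± 0.15 or lower and miR-127 at -2.46 ± 0.13 or lower. miR-195 of the miR-15/16 family (-3.74 ± 0.26), miR-30e (-3.99 ± 0.25), hsa-miR-188 (-3.86 ± 0.68) and mmu-miR-294 (-3.59 ± 0.53) also fell. The assay miR-26a fell (-3.36 ± 0.19), but its second assay, miR-26aN, differed by 0.04. Of 8 let-7 members, which restrain growth in differentiated cells, 3 fell with the scaling used, but with no scaling 5 rose and 0 fell, and with quantile normalization 5 fell and 2 rose (camera adjusted p = 0.0280, and adjusted p = 0.179 with an estimated correlation). Adjusted over the list alone 3 fell: mmu-let-7f (-3.61 ± 0.44, against at least 0.40 for the second assay let-7f), let-7b (-1.41 ± 0.18) and let-7c (-1.24 ± 0.23). let-7b turned to 1.30, let-7c to 1.475 and miR-146 from -2.46 ± 0.33 to 0.125 with no scaling. Among markers of other cells, the endothelial miR-126 rose by at least 1.54 and 2 of 2 mesenchymal assays rose.

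In all, 77 of 127 tested assays passed limma's test, 59 higher in myoblasts and 18 lower. With quantile normalization the split was 60 to 33, with no scaling 6 of 112 calls were lower, and the median difference of all tested assays was 1.09, or 3.85 with no scaling. A detection limit of Ct 32 left 50 calls, and 29 of the 77 calls rest on an assay that a whole group missed. The MuSC samples differed by an SD of 1.17 to 1.28 Ct against 0.324 to 1.09 within other groups.

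From LT-HSC to KSL-B6, the miRNAs encoded in the Hox clusters rose together. All 4 measured assays rose, and 4 when adjusted over the list alone, but as a list they did not stand apart (camera adjusted p = 0.114, and adjusted p = 0.284 with an estimated correlation). miR-196a rose by at least 7.35 ± 0.11, miR-196b by at least 6.65 ± 0.29 and miR-10a by 5.11 ± 0.39 (n = 3 KSL-B6 and 4 LT-HSC). Of 12 measured miRNAs known as high in blood stem cells, 11 were higher in KSL-B6, and 11 when adjusted over the list alone (camera adjusted p = 0.0739, and adjusted p = 0.284 with an estimated correlation). Among them were miR-126 (5.60 ± 1.29), miR-125a (5.30 ± 1.19), miR-155 (at least 3.55 ± 0.11), miR-100 (at least 3.38 ± 0.23) and miR-99a (at least 2.98 ± 0.19). The miR-17 family had 8 of 13 members higher, and 9 when adjusted over the list alone (camera adjusted p = 0.142, and adjusted p = 0.284 with an estimated correlation), with mmu-miR-106a at 5.66 ± 0.32 and miR-93 at 4.73 ± 0.82. miR-181bN (at least 5.31 ± 0.14), miR-23bN (4.74 ± 0.27) and miR-27bN (4.30 ± 1.35) rose too.

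LT-HSC in turn had more miR-223, the granulocyte miRNA, at Ct 19.1 ± 0.263 (SD, n = 4) against 20.8 ± 0.265 (SD, n = 3) in KSL-B6, a scaled difference of -3.68 ± 0.20. It was the 1 called assay among 4 of the myeloid markers, while of 3 lymphoid marker assays 2 rose and 1 fell. The largest falls were those of miR-321 (-6.59 ± 0.21), miR-375 (-5.85 ± 0.67) and miR-29bN (-5.32 ± 0.22). mmu-miR-192 fell (-5.02 ± 0.25 or lower) where its second assay differed by -0.44. miR-212 (-4.85 ± 0.28 or lower), miR-30e-3p (-4.38 ± 0.38), mmu-miR-463 (-3.80 ± 0.49 or lower), hsa-miR-520h (-3.16 ± 0.43) and hsa-miR-188 (-2.75 ± 0.25 or lower) fell as well. limma called 78 of 121 tested assays, 60 higher in KSL-B6 and 18 lower. The call of miR-27bN ended when any 1 of 5 of the 7 libraries was left out (adjusted p up to 0.0914, without KSL-B6 replicate 1). The split was 51 to 29 with quantile normalization, 86 to 11 with no scaling and 37 to 23 centred on the median of common assays, with median differences of 0.97, 3.27 and 0.37 against 1.14.

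The muscle and blood steps were set against each other to ask whether leaving the stem cell state changes the same miRNAs. Of 99 assays tested in both, 45 rose in the muscle step and 55 in the blood step, and 27 rose in both where 25 would by chance (Fisher's exact p = 0.543, two-sided). Another 14 and 13 fell, with 2 in common, miR-29bN and hsa-miR-188, where 1.84 would by chance (Fisher's exact p = 1), and 11 were called in opposite directions. Across assays, which are not independent replicates, r was 0.247 and rho 0.238, and 61.6% had the same sign. The shared rises numbered 17 with a detection limit of Ct 32 and 65 with no scaling. Leaving out either MuSC sample gave 6 shared falls, and leaving out LT-HSC replicate 4 gave 4.

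The difference between the steps was itself tested as an interaction. Both assays of miR-31 lay lower in the blood step (-11.20 ± 0.42 or lower for miR-31, and -8.41 ± 0.21 for hsa-miR-31, which both stem cell groups missed), as did miR-186 (-8.91 ± 0.65 or lower), miR-321 (-10.10 ± 0.39) and hsa-miR-520e (-7.04 ± 1.64). In the other direction stood miR-381 (5.21 ± 0.88), mmu-miR-294 (4.84 ± 0.71), the Hox cluster miRNAs miR-196a (at least 4.48 ± 0.83) and miR-10a (4.47 ± 0.39), and mmu-let-7f (at least 4.48 ± 0.51, with its second assay missed by both stem cell groups). Of 6 Dlk1-Dio3 members 5 lay higher in the blood step, and 5 when adjusted over the list alone (camera adjusted p = 0.000887, and adjusted p = 0.175 with an estimated correlation). For miR-134 (3.84 ± 0.23) and miR-379 (3.99 ± 0.59) both blood groups missed the assay, and for miR-127 (2.62 ± 0.21) LT-HSC and myoblasts did, so these values carry the muscle step alone or in part. limma called 82 of 149 assays, 25 higher and 57 lower in the blood step, or 44 and 45 with quantile normalization. The median difference was -0.74, -0.08 with quantile normalization and -0.52 centred on the median of common assays.

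**Figure D2:**
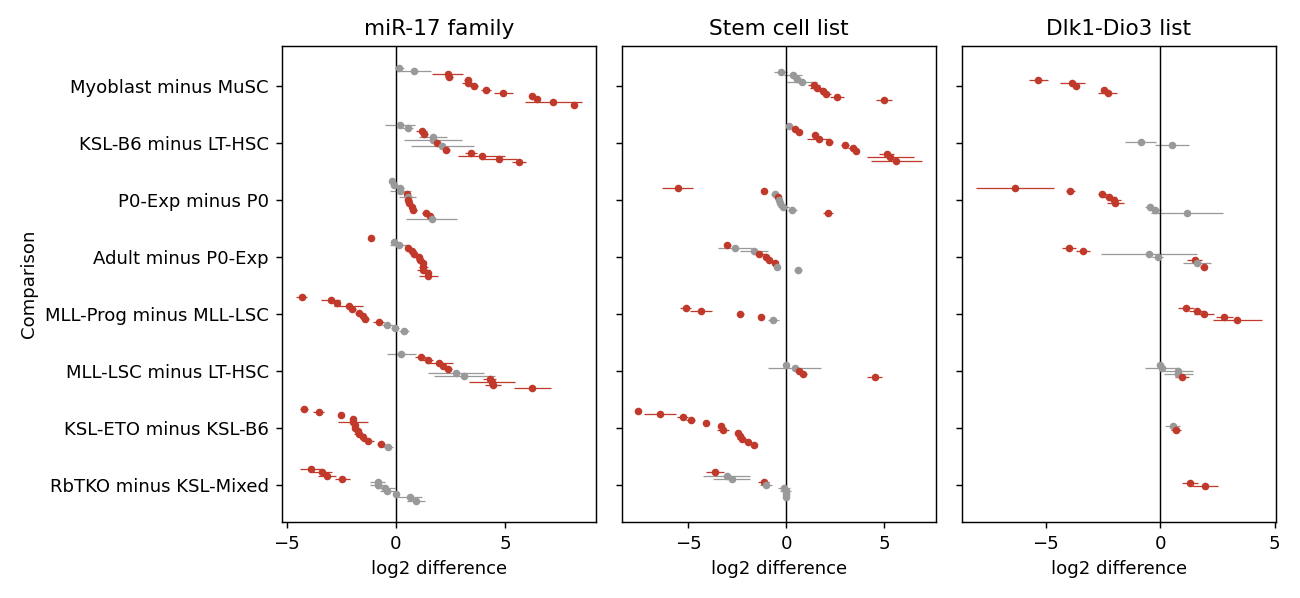
log2 difference (x axis) ± standard error of each tested member of the miR-17 family, the blood stem cell list and the Dlk1-Dio3 list in 8 comparisons (y axis); red points passed the test and grey points did not. In KSL-ETO all 12 stem cell list members lie below 0, and in myoblasts 11 of 13 miR-17 family members lie above 0 and pass the test, with the scaling used.

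Newborn neural cells expanded as neurospheres had less of several miRNAs known from other cell types than the fresh isolates. The lymphocyte miRNA miR-150 fell (-7.40 ± 0.88, n = 3 and 3), as did miR-126 (-5.53 ± 0.79) and its partner strand miR-126* (-5.56 ± 0.46), which come from the endothelial gene Egfl7, and miR-142-3p (-2.48 ± 0.51 or lower). Of the hematopoietic list miR-223 did not pass (-3.46 ± 1.88, adjusted p = 0.211), with 1 expanded run at Ct 27.6 against 27.3 to 29.7 in fresh runs, and mmu-miR-155 rose (2.11 ± 0.26). miR-204 (-9.99 ± 1.70), a miRNA of the choroid plexus, showed the largest fall. The epithelial marker miR-375 (-6.12 ± 1.16) and hsa-miR-449 (-4.62 ± 1.35), known from ciliated cells, fell as well. Both mesenchymal markers, miR-143 (-2.65 ± 0.28 or lower) and miR-145 (-2.03 ± 0.27), fell. miR-7 (-3.83 ± 0.65) and miR-135b (-3.43 ± 0.17) fell too. Of 9 Dlk1-Dio3 members 6 fell, and 6 when adjusted over the list alone (camera adjusted p = 0.0312, and adjusted p = 0.352 with an estimated correlation), with hsa-miR-433 at -3.92 ± 0.18 or lower, mmu-miR-379 at -2.52 ± 0.18 or lower, miR-134 at -2.23 ± 0.31 and miR-370 at -6.32 ± 1.71.

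In the other direction, expansion raised both assays of miR-31 (5.20 ± 0.30 and 3.01 ± 0.44) and the miR-29 family members miR-29a (at least 3.92 ± 0.18) and miR-29c (2.97 ± 0.24). miR-27a (4.26 ± 0.23), hsa-miR-146b (3.91 ± 0.18), miR-186 (4.67 ± 1.45), mmu-leuk-mir-9 (3.01 ± 0.24), miR-34aN (2.60 ± 0.44) and the neuronal miR-132 (2.27 ± 0.19) rose. Of 13 miR-17 family members 7 rose, and 7 when adjusted over the list alone, but centred on the median of common assays 2 rose and 2 fell (camera adjusted p = 0.0163, and adjusted p = 0.352 with an estimated correlation). mmu-miR-106a rose by 1.57 ± 0.13 (second assay 1.64, not called), mmu-miR-93 by 1.37 ± 0.19 (second assay 0.21, not called) and hsa-miR-20b by at least 0.59 ± 0.12. Of 5 measured miRNAs known as high in MLL-rearranged leukaemia 4 rose, and 4 when adjusted over the list alone (camera adjusted p = 0.0504, and adjusted p = 0.352 with an estimated correlation). They included mmu-miR-155 and, also on the miR-17 family list, miR-92 (0.81 ± 0.18) and miR-19b (0.51 ± 0.14).

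limma called 59 of 126 assays, 27 higher and 32 lower after expansion, against 45 and 22 with no scaling and 17 and 51 centred on the median of common assays. It called 36 in all when no assay was left out as undetected. The median difference was -0.23, 0.33 and -0.70 under these 3 scalings. The calls of miR-186, miR-370, hsa-miR-449, miR-19b, miR-92 and hsa-miR-20b ended in up to 5 of 6 fits with 1 library left out (adjusted p up to 0.149, for miR-186 without NSPC-P0-Exp replicate 1).

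Adult neurospheres were compared with newborn ones in the same culture form. NSPC-Adult replicates 2 and 3 carry the strain labels C57/Bl7 and C57/Bl8. Of 8 let-7 members 5 were higher, and 5 when adjusted over the list alone, but as a list they did not stand apart (camera adjusted p = 0.299, and adjusted p = 0.486 with an estimated correlation), with let-7f at 2.69 ± 0.56, let-7a at 1.89 ± 0.34 and let-7d at 1.86 ± 0.25 (n = 3 and 3). The brain miRNA miR-128a rose by 3.33 ± 0.60, miR-375 by 3.69 ± 0.86, miR-301 by 2.79 ± 0.20 and miR-143 by at least 1.94 ± 0.26. Of the p53 targets, miR-34c rose by 2.89 ± 0.33 and miR-34a by at least 2.74 ± 0.16, although the second miR-34a assay differed by -0.66. The miR-17 family had 10 of 13 members higher and 1 lower, and 10 and 1 when adjusted over the list alone (camera adjusted p = 0.0923, and adjusted p = 0.311 with an estimated correlation). miR-93 (1.46 ± 0.12) and miR-106b (1.06 ± 0.11) rose and hsa-miR-20b fell (-1.14 ± 0.11 or lower).

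Of 9 members of the blood stem cell list 5 were lower in adult neurospheres, and 7 fell and 1 rose when adjusted over the list alone, but with no scaling 1 fell and 1 rose (camera adjusted p = 0.00116, and adjusted p = 0.238 with an estimated correlation). mmu-miR-99a stood at -3.01 ± 0.18, miR-100 at -1.04 ± 0.12 and miR-99a at -0.87 ± 0.10. The Dlk1-Dio3 members divided, with miR-127 (-3.97 ± 0.30) and miR-134 (-3.38 ± 0.30 or lower) lower and hsa-miR-431 (at least 1.90 ± 0.14, second assay 1.63, not called) higher, among 2 lower and 2 higher of 7 (camera adjusted p = 0.997 preset and estimated). HSA-leuk-mir-7 (-3.84 ± 0.12 or lower), miR-135b (-3.57 ± 0.87), miR-132 (-3.51 ± 0.69), mmu-miR-383 (-3.24 ± 0.25 or lower), hsa-miR-525 (-2.91 ± 0.63) and hsa-miR-516-3p (-1.94 ± 0.31) fell, and hsa-miR-31 fell (-2.11 ± 0.39) where its second assay differed by -0.51. limma called 54 of 132 assays, 34 higher and 20 lower in adult cells, and 86 without NSPC-P0-Exp replicate 3. The calls of miR-375, miR-135b and hsa-miR-525 ended in 4, 2 and 3 of 6 fits with 1 library left out (adjusted p up to 0.0825, 0.0825 and 0.0677, each without NSPC-P0-Exp replicate 1). With no scaling the split was 61 to 14 and the median difference 1.13, against 0.46 and against 0.34 with quantile normalization.

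The normal populations were then compared by tissue to find miRNAs that differ between blood, muscle and brain, with each assay that a group missed held at the lowest level common to the runs. Blood and muscle stand for 2 populations each and brain for 3, so tissue cannot be told apart from these populations. Blood had 6 of 7 hematopoietic assays higher than the other tissues, and 6 when adjusted over the list alone (camera adjusted p = 5.59e-06, and adjusted p = 0.00106 with an estimated correlation). miR-223 stood 11.39 ± 0.57 above muscle and brain, miR-150 6.51 ± 0.33, miR-142-3p 6.40 ± 0.22 and miR-142-5p 5.17 ± 0.19 (n = 7 and 15), while a second assay, mmu-miR-142-3p, differed by 0.49 ± 0.29. The myeloid markers (3 of 4 higher, camera adjusted p = 0.00110) and the lymphoid markers (3 of 3 higher, camera adjusted p = 0.00472) kept adjusted p = 0.01004 and adjusted p = 0.0442 with an estimated correlation. Both lists share assays with the hematopoietic list, such as miR-223 and miR-142-3p (myeloid) and miR-150 and miR-155 (lymphoid). They are thus no separate support. miR-155 was higher by 1.08 ± 0.08 and 0.95 ± 0.17 in its 2 assays, but LT-HSC missed the first, and by Ct the second came no earlier in LT-HSC (29.7) than in myoblasts (27.45). Of 9 miRNAs of MLL-rearranged leukaemia 4 were higher, or 6 with 1 lower under quantile normalization or no scaling (camera adjusted p = 0.00470, and adjusted p = 0.0167 with an estimated correlation), including miR-10a (2.67 ± 0.15) and miR-92 (1.04 ± 0.11, against -0.13 in its second assay). miR-146, which dampens NF-kB signalling, was higher by 3.94 ± 0.19 and miR-191 by 2.31 ± 0.51.

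Blood lay below the other tissues in miR-100 (-5.16 ± 0.17), miR-125b (-4.64 ± 0.11) and miR-30a-3p (-4.11 ± 0.09). Of 8 let-7 members 6 were lower and 1 higher, and 7 and 1 when adjusted over the list alone (camera adjusted p = 0.189, and adjusted p = 0.2755 with an estimated correlation), with let-7b at -3.23 ± 0.17 and let-7c at -3.07 ± 0.11. All 3 assays of the miR-23/27/24 clusters (camera adjusted p = 0.226, and adjusted p = 0.2755 with an estimated correlation) and 3 of 4 mesenchymal markers (camera adjusted p = 0.226, and adjusted p = 0.344 with an estimated correlation) were lower, such as miR-24 at -1.54 ± 0.13 and miR-214 at -2.09 ± 0.26. Of the neural list miR-132 was lower (-1.63 ± 0.24) and miR-212 higher (1.198 ± 0.47), but miR-212 lost its call in 10 of 22 fits with 1 library left out (adjusted p up to 0.192). limma called 105 of 169 assays, 33 higher and 72 lower, of which 69 differed by at least 1 log2 unit. Of these calls 62 involve an assay that a whole group missed. Only 12 of the 169 tested assays were called with all blood samples apart. With populations kept whole, chance sets 9.52% of assays apart if none are tied at the floor. That share also counts assays that are not called, so it is not a like measure for these 12. With quantile normalization the split was 43 to 59, and the median difference was -0.41, -0.14 with quantile normalization, -0.52 with no scaling and -0.26 centred on the median of common assays.

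Muscle had more miR-206 (8.72 ± 0.12, n = 6 and 16) and miR-1 (1.02 ± 0.29, from myoblasts alone), the 2 tested members of the muscle list, and miR-206 was lower in blood and in neural cells (-4.36 ± 0.11 in each). miR-199a* (5.40 ± 0.14) and miR-214 (4.19 ± 0.27) were higher, as were all 3 tested assays of the miR-23/27/24 clusters (camera adjusted p = 0.240, and adjusted p = 0.316 with an estimated correlation), with miR-24 at 2.66 ± 0.14, and the further assay miR-27bN at 3.08 ± 0.58. miR-146 (-5.08 ± 0.20), hsa-miR-146b (-4.71 ± 0.25) and miR-132 (-1.22 ± 0.25) were lower. Of 7 hematopoietic assays 4 were lower and 1 higher (camera adjusted p = 0.0447, and adjusted p = 0.0977 with an estimated correlation), with miR-223 at -6.92 ± 0.60, miR-150 at -4.78 ± 0.35 and miR-142-3p at -3.45 ± 0.23 (second assay -0.24). The higher one, mmu-miR-155 (0.50 ± 0.18), turned to -0.40 with no scaling and lost its call when any 1 of 4 of the 22 libraries was left out (adjusted p up to 0.115, without LT-HSC replicate 3). limma called 86 of 169 assays, 51 higher and 35 lower, against 37 and 61 with no scaling. Of these calls 48 involve an assay that a whole group missed. Only 9 of the 169 tested assays were called with all muscle samples apart. The 9.52% by chance, which also counts assays not called and assumes no ties, is again not a like measure. The median difference was 0, -0.53 with no scaling and -0.25 with quantile normalization.

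Neural cells had more miR-218 (5.76 ± 0.56, n = 9 and 13), miR-99a (3.98 ± 0.25), let-7c (2.44 ± 0.10), hsa-miR-181b (1.70 ± 0.09) and miR-30c (1.64 ± 0.18). Of 4 tested members of the neural list 1 was higher, miR-132 at 2.84 ± 0.22 (camera adjusted p = 0.462, and adjusted p = 0.495 with an estimated correlation), while mmu-miR-137 differed by 0.49 ± 0.23, miR-128a by 0.13 ± 0.31 and miR-212 by -0.00429 ± 0.45. No assay of miR-9 or miR-124 was detected in the 9 neural runs, with the earliest signal at Ct 35. The assays mmu-miR-9, miR-124a and mmu-miR-124a were detected in no other group either. Absence thus cannot be told apart from an assay that does not work. The Hox cluster miRNAs were lower in 3 of 4 assays (camera adjusted p = 0.0843, and adjusted p = 0.177 with an estimated correlation), with miR-196a at -4.29 ± 0.24, miR-196b at -3.40 ± 0.43 and miR-10a at -1.33 ± 0.14. Hematopoietic assays were lower in 6 of 7 (camera adjusted p = 0.00730, and adjusted p = 0.0358 with an estimated correlation), myeloid markers in 3 of 4 and lymphoid markers in 3 of 3 (camera adjusted p = 0.0783 for both). The 3 tissue differences of an assay sum to 0, so the hematopoietic falls here and in muscle mirror the rise in blood and are no separate findings. Against muscle alone the direction varied. By Ct, miR-150 came earlier in NSPC-P0 (25.7) than in MuSC (33.2) or myoblasts (32.3), while mmu-miR-155 came later in NSPC-P0 (30.4) than in myoblasts (27.45). miR-191 was lower by -2.70 ± 0.48. limma called 105 of 169 assays, 57 higher and 48 lower, 69 of them by at least 1 log2 unit. Of these calls 62 involve an assay that a whole group missed. Only 6 of the 169 tested assays were called with all neural samples apart. The 5.71% by chance, which also counts assays not called and assumes no ties, is not a like measure here either. With no scaling the split was 89 to 44 and the median difference 0.73 against 0.12.

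**Figure D3:**
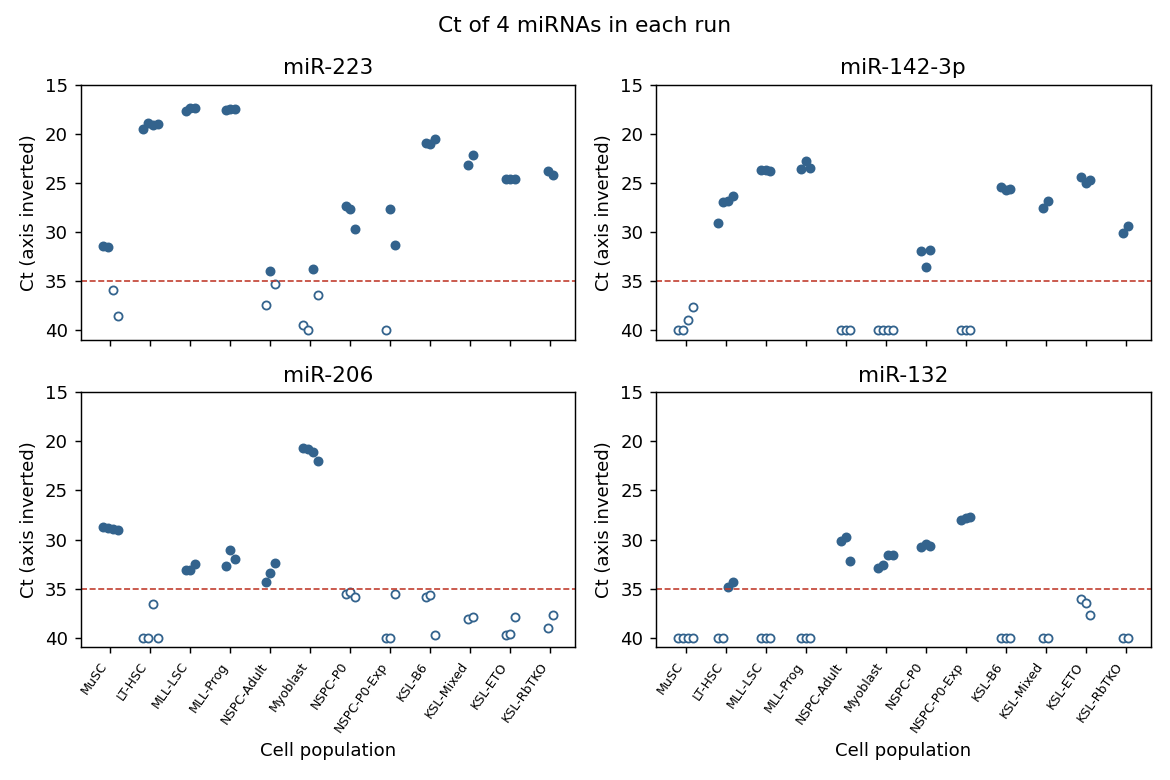
Ct (y axis, inverted so that more RNA lies higher) of miR-223, miR-142-3p, miR-206 and miR-132 in each run of the 12 cell populations (x axis); filled points were detected, open points were not, and the dashed line marks Ct 35. miR-223 lies at Ct 18.9 to 19.5 in LT-HSC and at 24.6 in each KSL-ETO run.

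Within MLL-AF10 leukaemia, the Kit+ stem cells and the Kit- cells differed in the miRNAs known from this leukaemia. Of 8 measured members 7 were lower in Kit- cells, and 7 when adjusted over the list alone (camera adjusted p = 0.000564, and adjusted p = 0.339 with an estimated correlation). The 3 Hox cluster assays fell, with miR-10a at -5.13 ± 0.29, miR-196b at -1.96 ± 0.14 and miR-196a at -0.83 ± 0.13 (n = 3 and 3), and 4 of 5 members of the blood stem cell list fell (camera adjusted p = 0.0296 and 0.0164, and adjusted p = 0.339 with an estimated correlation for both). Of 12 miR-17 family members 9 fell, or 7 with 1 rise centred on the median of common assays (camera adjusted p = 0.00501, and adjusted p = 0.339 with an estimated correlation), with mmu-miR-106a at -4.33 ± 0.26, mmu-miR-93 at -2.99 ± 0.43, miR-17-5p at -2.72 ± 0.15 or lower and miR-19a at -1.99 ± 0.15. miR-126 (-4.35 ± 0.55), miR-148a (-4.16 ± 0.67), let-7b (-3.59 ± 0.38), miR-30e-3p (-2.86 ± 0.46), let-7d (-2.69 ± 0.78) and miR-23bN (-2.59 ± 0.34) fell too. The assay miR-155 fell (-2.35 ± 0.18 or lower) where its second assay differed by -0.66.

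Kit- cells had more of the myeloid markers, in 4 of 4 assays with the scaling used and in 0 of 4 with no scaling (camera adjusted p = 0.0296, and adjusted p = 0.339 with an estimated correlation). miR-142-3p rose by 1.27 ± 0.20 and miR-223 by 0.77 ± 0.15, but miR-223 stood at -0.07 with no scaling, since its Ct was 17.5 in both. All 5 Dlk1-Dio3 members rose, or 1 with no scaling (camera adjusted p = 0.0296, and adjusted p = 0.339 with an estimated correlation), among them hsa-miR-431 (2.81 ± 0.36), miR-370 (1.91 ± 0.45) and hsa-miR-432 (3.37 ± 1.06). Adjusted over the list alone the counts were 3 Hox cluster, 4 stem cell list and 9 miR-17 family falls, and 4 myeloid and 5 Dlk1-Dio3 rises. miR-149 (2.91 ± 0.45), miR-218 (2.71 ± 0.45), miR-200c (2.31 ± 0.49), miR-184 (at least 2.12 ± 0.17), mmu-miR-294 (2.04 ± 0.66) and miR-373 (2.01 ± 0.53) rose. limma called 70 of 122 assays, 34 higher and 36 lower in Kit- cells (4 and 61 with no scaling, 42 and 26 centred on the median of common assays), 45 when no assay was left out as undetected and 39 with all groups in 1 fit. The median difference was -0.08, -0.90 with no scaling, 0.35 centred on the median of common assays and 0.17 with quantile normalization. The calls of hsa-miR-432, mmu-miR-294, miR-373, let-7d and miR-370 ended in 2 to 5 of 6 fits with 1 library left out (adjusted p up to 0.124, for mmu-miR-294 without MLL-LSC replicate 2).

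Set against normal LT-HSC, the leukaemia stem cells had far more Hox cluster miRNAs, a rise that normal KSL-B6 also showed over LT-HSC. All 3 measured assays rose, and 3 when adjusted over the list alone (camera adjusted p = 0.0419, and adjusted p = 0.548 with an estimated correlation). miR-196b rose by at least 9.55 ± 0.14, miR-196a by at least 9.48 ± 0.14 and miR-10a by 4.498 ± 0.39 (n = 3 and 4). Of 12 miR-17 family members 9 rose, and 9 when adjusted over the list alone (camera adjusted p = 0.129, and adjusted p = 0.600 with an estimated correlation), with miR-93 at 6.26 ± 0.84, mmu-miR-106a at 4.44 ± 0.37, miR-106a at 4.31 ± 0.30 or above and miR-20 at 2.39 ± 0.18. Of 8 miRNAs known from MLL-rearranged leukaemia 7 rose, and 7 when adjusted over the list alone (camera adjusted p = 0.129, and adjusted p = 0.548 with an estimated correlation). miR-181bN (at least 6.68 ± 0.17), miR-15b (5.53 ± 0.77) and let-7g (at least 4.81 ± 0.18) rose as well. Normal KSL-B6 also lay above LT-HSC in miR-93 (4.73), mmu-miR-106a (5.66) and miR-181bN (at least 5.31). These rises over LT-HSC and those of the Hox cluster miRNAs were thus not seen in the leukaemia cells alone. Both comparisons use the same 4 LT-HSC samples, so low values in LT-HSC could give both rises. MLL-LSC and KSL-B6 were not compared directly.

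LT-HSC had more miR-150 (-6.41 ± 0.26), miR-29bN (-5.32 ± 0.24), miR-375 (-4.36 ± 0.93), miR-130aN (-4.27 ± 0.58), miR-321 (-4.00 ± 0.27), miR-31 (-3.89 ± 0.34 or lower) and miR-212 (-3.64 ± 0.58) than the leukaemia stem cells. mmu-miR-463 (-3.77 ± 0.49 or lower) and hsa-miR-520h (-3.52 ± 0.33 or lower) went the same way, as did mmu-miR-192 (-4.99 ± 0.26 or lower), whose second assay differed by 1.93. The second assay of miR-31, hsa-miR-31, was detected in no run of either group. limma called 66 of 123 assays, 50 higher and 16 lower in MLL-LSC (107 with no scaling), and 42 with a detection limit of Ct 32. The split was 43 to 26 with quantile normalization, 93 to 14 with no scaling and 29 to 20 centred on the median of common assays, with median differences of 0.54, 2.89 and 0.05 against 0.80.

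Progenitors carrying the AML-ETO9a transgene had less of the blood stem cell miRNAs than KSL-B6. All 12 measured members of that list fell against KSL-B6, and 12 when adjusted over the list alone (camera adjusted p = 9.95e-05, and adjusted p = 0.270 with an estimated correlation), including miR-10a (-7.54 ± 0.12 or lower), miR-125a (-6.43 ± 0.80), miR-100 (-5.28 ± 0.27 or lower), miR-99b (-4.08 ± 0.11 or lower) and miR-125b (-3.34 ± 0.15 or lower, n = 3 and 3). Against KSL-Mixed miR-10a, miR-100, miR-99b and miR-125b stood at -6.37, -1.72, -1.92 and -1.57 or lower, and miR-125a at -5.97. The Hox cluster miRNAs fell in 4 of 4 assays, and 4 when adjusted over the list alone (camera adjusted p = 0.00907, and adjusted p = 0.277 with an estimated correlation), with miR-196a at -9.24 ± 0.11 or lower and miR-196b at -8.54 ± 0.30 or lower. Of 13 miR-17 family members 12 fell, and 12 when adjusted over the list alone (camera adjusted p = 0.00200, and adjusted p = 0.277 with an estimated correlation), with hsa-miR-20b at -4.21 ± 0.18 or lower, miR-92 at -2.51 ± 0.14 and miR-19b at -1.88 ± 0.11. With KSL-Mixed as control 7 of 12 family members fell and 1, miR-17-5p, rose. mmu-miR-221 (-7.98 ± 0.65) and miR-222 (-6.88 ± 0.39), which target Kit, fell, as did miR-130aN (-8.13 ± 0.20), miR-181bN (-7.21 ± 0.16 or lower) and miR-203 (-6.78 ± 0.17 or lower).

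The same cells gained miR-31, by 6.09 ± 0.15 and 5.56 ± 0.17 in its 2 assays, and hsa-miR-31 reached Ct 22.6 ± 0.0577 against 28.2 ± 0.153 (SD, n = 3 each). miR-183 (at least 6.17 ± 0.12), miR-296 (4.82 ± 0.17), miR-27a (3.46 ± 0.18) and the hypoxia miRNA miR-210N (3.32 ± 0.11) rose. miR-340 (3.22 ± 0.86), miR-152 (3.196 ± 0.51), miR-301 (2.93 ± 0.87) and miR-200cN (2.83 ± 0.37) rose too. Myeloid markers went both ways, with miR-142-3p up by 1.36 ± 0.13 and miR-223 at -3.31 ± 0.16, in 3 rises and 1 fall of 4 (camera adjusted p = 0.418, and adjusted p = 0.586 with an estimated correlation). The lymphoid markers fell in 3 of 3 assays (camera adjusted p = 0.187, and adjusted p = 0.586 with an estimated correlation), with miR-155 at -3.24 ± 0.30 and miR-150 at -0.94 ± 0.17. Of 9 miRNAs of MLL-rearranged leukaemia 7 fell and 1 rose (camera adjusted p = 0.0221, and adjusted p = 0.270 with an estimated correlation). limma called 88 of 125 assays, 40 higher and 48 lower, against 58 and 41 with quantile normalization and 24 and 59 with no scaling. The median differences were -0.01, 0.47 and -0.50, and 0.20 centred on the median of common assays. The calls of miR-301 and miR-340 ended in 4 and in 2 of 6 fits with 1 library left out (adjusted p up to 0.101 and 0.0734, both without KSL-B6 replicate 2).

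Loss of the Rb family was set against KSL-Mixed, progenitors of the same mixed strain. The Hox cluster miRNAs were lower in 3 of 3 assays, and 3 when adjusted over the list alone (camera adjusted p = 0.323, and adjusted p = 0.871 with an estimated correlation), with miR-196b at -4.85 ± 0.42 or lower, miR-196a at -3.69 ± 0.72 and miR-10a at -3.64 ± 0.44 (n = 2 and 2). Of 11 members of the miR-17 family, which E2F factors induce, 4 were lower, but with quantile normalization 1 was lower and 1 higher (camera adjusted p = 0.548, and adjusted p = 0.871 with an estimated correlation). miR-93 stood at -3.89 ± 0.51 and mmu-miR-106a at -3.14 ± 0.42, with their second assays missed in KSL-RbTKO, and miR-19a at -3.39 ± 0.46. miR-130aN (-3.54 ± 0.85), miR-203 (-3.40 ± 0.32 or lower), miR-27bN (-3.50 ± 0.42 or lower, second assay -1.15) and let-7b (-2.49 ± 0.37) were lower.

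Assays higher in KSL-RbTKO included HSA-leuk-mir-7 (2.91 ± 0.37), mmu-miR-383 (2.51 ± 0.34), mmu-miR-294 (2.46 ± 0.36), let-7i (2.21 ± 0.34), miR-145 (2.11 ± 0.46), miR-29bN (2.01 ± 0.30) and miR-381 (1.96 ± 0.57). With no scaling 0 assays were higher and 61 lower, and miR-145 (-0.10), miR-29bN (-0.20) and miR-381 (-0.25) turned negative. Of the 15 higher assays, 5 target a miRNA cluster known from primates alone, among them hsa-miR-520h (2.41 ± 0.36), hsa-miR-516-3p (2.11 ± 0.38) and hsa-miR-520e (2.01 ± 0.35), of which the last pair turned to -0.10 and -0.20 with no scaling. Each assay named in this comparison lost its call in at least 2 of the 4 fits with 1 library left out (adjusted p up to 0.449, for miR-381 without KSL-Mixed replicate 4). limma called 40 of 94 assays, 15 higher and 25 lower (20 and 12 centred on the median of common assays), and 25 in all without the primate cluster assays. The count was 25 without KSL-RbTKO replicate 1, 26 without KSL-RbTKO replicate 2, 18 without KSL-Mixed replicate 4 and 0 without KSL-Mixed replicate 5 (24 at an unadjusted p under 0.05), and 2 when no assay was left out as undetected. The commonly detected assays lay 2.21 cycles later in KSL-RbTKO, and the median difference was -0.34, -0.61 with quantile normalization, -2.48 with no scaling and 0 centred on the median of common assays.

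Wildtype progenitors of both strains were compared to size a difference that involves no mutation. KSL-Mixed lay below KSL-B6 in both assays of miR-31 (-4.57 ± 0.17 or lower and -2.89 ± 0.22), in miR-15b (-4.48 ± 0.38), mmu-miR-93 (-3.78 ± 0.53) and miR-106a (-3.24 ± 0.53, second assay -0.74). It lay above KSL-B6 in hsa-miR-520e (2.69 ± 0.34), miR-145 (2.62 ± 0.39), mmu-miR-431 (2.54 ± 0.26), hsa-miR-522 (2.51 ± 0.28) and let-7i (2.47 ± 0.17, n = 2 and 3). Of 13 miR-17 family members 7 were lower, or 4 with 1 higher centred on the median of common assays (camera adjusted p = 0.385, and adjusted p = 0.9195 with an estimated correlation). limma called 53 of 115 assays, 19 higher and 34 lower, but 0 higher and 96 lower with no scaling and 28 and 18 centred on the median of common assays, with median differences of -0.16, -2.27 and 0.23. The count was 34 when no assay was left out as undetected and 31 with all groups in 1 fit, and miR-106a lost its call without KSL-Mixed replicate 5 (adjusted p 0.0673).

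The 27 assays that rose in both the muscle and the blood step were followed through the other comparisons. As a list they were lower in KSL-ETO than in KSL-B6, by a mean of -2.09 over 27 assays with 20 falls and 3 rises (camera adjusted p = 0.00227, and adjusted p = 0.111 with an estimated correlation). KSL-B6 also helped define the list, and unchanged groups simulated against it gave a mean of -0.0065, between -0.213 and 0.224, in 100 sets. Against KSL-Mixed the mean was -0.19 and did not pass. The list was lower in Kit- than in Kit+ leukaemia cells (-1.34 over 20 assays, 11 falls and 2 rises, camera adjusted p = 0.00400, and adjusted p = 0.259 with an estimated correlation). It was lower in KSL-RbTKO (-1.24 over 19 assays, 6 falls, camera adjusted p = 0.0126, and adjusted p = 0.259 with an estimated correlation), though not without KSL-Mixed replicate 5 (-1.07). It was higher in expanded than in fresh newborn neural cells (0.34 over 27 assays, 13 rises and 2 falls, camera adjusted p = 0.000862, and adjusted p = 0.0555 with an estimated correlation), with a mean of 0.11 without NSPC-P0-Exp replicate 3 and of -0.14 centred on the median of common assays. A list drawn from the muscle step alone did not pass in KSL-ETO or in the leukaemia cells.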

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

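The tests for a sample far from the others and for a difference between the steps were both planned. Of 72 groups of 4 samples tested, 6 had a sample whose gap to its nearest neighbour exceeded the critical share of the group's range, and chance gives about 1 in 20. In LT-HSC against KSL-B6, the gap was the whole range (1) for mmu-miR-106a and miR-23bN, which LT-HSC replicate 2 alone detected (Ct 33.3 and 33.9). It was the whole range (1) also for miR-125a, which LT-HSC replicate 3 alone detected (Ct 29.8). It was 0.864 for mmu-miR-192 in LT-HSC replicate 4 (Ct 29.6) and 0.842 for hsa-miR-520h in LT-HSC replicate 1 (Ct 30.6). In LT-HSC against MLL-LSC it was again 1 for mmu-miR-106a. Where the other samples all lay at the common floor the gap is 1 by construction, so the finds at 1 cannot be set against that chance share. None of the 6 was weighed further.

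The blood step from LT-HSC to KSL-B6 and the muscle step from MuSC to myoblasts differed in 82 assays by limma's test of the difference itself. The change was more positive in the blood step for miR-381 (5.21), mmu-miR-294 (4.84), miR-196a (at least 4.48), mmu-let-7f (at least 4.48) and miR-10a (4.47). The same held for miR-379 (3.99), miR-134 (3.84) and miR-127 (2.62). Both blood groups missed miR-379 and miR-134, so their values carry the muscle step alone. The change was more positive in the muscle step for miR-31 (-11.20 or lower), miR-321 (-10.10), miR-186 (-8.91 or lower), hsa-miR-31 (-8.41) and hsa-miR-520e (-7.04). These differences were not weighed further, and the tissue and the sorting differ together between the steps.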

How the results depend on the processing

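Of 395 alternative values of comparisons and lists, 356 were counted as kept. A list mean had to keep its direction and side of the threshold, and a count only had to stay within 1.5 times. Direction was ignored for counts. With no scaling the MLL cells gave 4 higher and 61 lower, against 34 and 36, and still counted as kept. So did strain centred on the median of common assays, with 28 and 18 against 19 and 34. Centring on the median of common assays, leaving out the primate cluster assays, treating the 4 MuSC runs as separate, leaving out assays with raw Ct differences below 0.5 and fitting unrounded values were chosen after seeing the data, as were those for the shared lists with no scaling. With a detection limit of Ct 32, where fewer assays were tested, MuSC against myoblasts gave 50 calls, LT-HSC against MLL-LSC 42 and the shared rises 17. With all assays tested, which adds undetected ones to the adjustment, NSPC-P0 against NSPC-P0-Exp gave 36, the MLL cells 45, KSL-RbTKO 2 and strain 34. With all groups in 1 fit the MLL cells gave 39 and strain 31. With no scaling, or centred on the median of all assays, LT-HSC against MLL-LSC gave 107, KSL-RbTKO 61 and strain 96, as every difference then includes that in RNA amount. The shared rises numbered 65 with no scaling. A 2-fold filter left 69 for blood and 69 for neural cells by construction. A block for the replicate number gave 37 for NSPC-P0 against NSPC-P0-Exp, where the numbers do not pair the samples, and changed no other count by more than 1.5 times. Of 159 values of named assays, 13 lost their call with the block. For LT-HSC against MLL-LSC, where correlations pair the numbers, the values given come from the fit without the block. Without the primate cluster assays KSL-RbTKO gave 25.

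The 2 shared falls became 1 at Ct 32, 4 at Ct 38, 8 with quantile normalization, 0 with no scaling, 5 centred on the median of common assays and 4 without the primate cluster assays. The list of shared rises had a mean of -0.84 in the MLL cells and -1.29 in KSL-ETO when drawn from muscle alone, and -0.19 in KSL-ETO against KSL-Mixed, none past the threshold. In NSPC-P0-Exp it turned to -0.14 centred on the median of common assays. Leaving out 1 sample gave 43 to 86 calls for NSPC-P0-Exp against NSPC-Adult, 0 to 26 for KSL-RbTKO, 2 to 6 shared falls, and list means of -1.34 to -0.97 in KSL-RbTKO.

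Single assays reversed with no scaling, and equally centred on the median of all assays: miR-146 (0.125), let-7b (1.30) and let-7c (1.475) in myoblasts, miR-223 (-0.0667) in the MLL cells, miR-145 and hsa-miR-516-3p (-0.10 each), miR-29bN and hsa-miR-520e (-0.20 each) and miR-381 (-0.25) in KSL-RbTKO, and mmu-miR-155 (-0.40) in muscle. With no common floor miR-155 in muscle reversed to 0.825. Of 3020 values of named assays with 1 sample left out, 2872 kept their call, 142 lost it and 6 gained it. Except where construction is named, the cause was not tested. Centring on control small RNAs was not run, since the panel has none. No paired analysis was run for RbTKO and strain, where sample numbers are not shared, or for comparisons that include the merged MuSC runs. Depth limits what can be said of MuSC, LT-HSC and KSL-RbTKO, where 61 to 96 assays were detected.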

Other observations

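The tests of the 3 patterns below were all chosen after the result was seen, as was regrouping whole populations, and the recounts over other splits of the samples were planned. miR-223 was more abundant in LT-HSC (Ct 18.9 to 19.5) than in the other normal populations by raw Ct. Of 232 comparisons of paired assays for 1 miRNA, both were called in 86, with the same direction in 85, and 1 of the pair alone was called in 98.

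Of the 15 assays higher in KSL-RbTKO, 5 target primate miRNAs, and hsa-miR-522 was detected in all 37 runs. If their signal were background that does not follow RNA amount, it would also stay level between KSL-B6 and KSL-Mixed, where common assays came 2.04 cycles later in KSL-Mixed. Their median raw difference there was 0.467 cycles, toward more signal, with a range of -1.97 (hsa-miR-516-3p, SD 2.06 in KSL-B6) to 1.08, and that of the other 10 assays was 0.217. By this test background signal is a candidate explanation for most of both sets, lifted by the scaling of KSL-RbTKO samples whose common assays came 2.21 cycles later. Across all 37 runs, though, none of the 5 stayed level. hsa-miR-520e ran from Ct 22.3 to 40, hsa-miR-525 from 29 to 40 and hsa-miR-520h from 30.6 to 40. hsa-miR-522 ran from 24 to 30.8 and hsa-miR-516-3p from 25.9 to 30.9. The level of the other 10 across all runs was not weighed. Whether background covers the 5, hsa-miR-516-3p above all, is not settled. All of the other 10, and 3 of the 5, were also called higher in KSL-Mixed than in KSL-B6, where no mutation is involved. A rise of these assays after scaling thus does not need the loss of the Rb family. Whether that loss adds to the rise of the other 10 stays open, as untested.

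The fall of the stem cell list in KSL-ETO was far larger than the RNA amount explains: the median raw difference was -3.88 cycles, against -0.490 for common assays. Unusual controls as the whole cause are argued against by KSL-Mixed, against which 9 of 9 tested members were also lower. Their median there was -1.72, against -3.29 for all 12 from KSL-B6, and since KSL-ETO missed several, the size of the fall is not settled. Uniform dilution by other cells would lower every member alike, but the differences had an SD of 1.88 and ran from -7.54 to -1.64, with a median standard error of 0.168. An effect of the transgene, a change in the mix of cells within the sorted gate, and a difference between mice stay open, as untested.

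From NSPC-P0 to NSPC-P0-Exp, the blood and endothelial miRNAs called lower had a median raw difference of -5.17 cycles over 4 assays. They were chosen for their fall, and leave out miR-223, not called, and mmu-miR-155, which rose. Common assays came 0.561 cycles earlier after expansion, so a lower RNA amount is argued against. Cells like KSL-B6 as the only source of miR-223, miR-142-3p and miR-150 in the fresh isolate are argued against too. These lay 7.40, 6.87 and 1.17 cycles from their KSL-B6 levels, a range of 6.23. The range rests on miR-150, while the other offsets lie close together, so the test cannot exclude that such cells were present. Loss of other cells of the tissue in culture may explain the fall. Of 4 marker lists with calls, 3 had all called members lower, but these hold 1, 2 and 1 tested assays, and of 4 in the hematopoietic list 2 were lower and mmu-miR-155 higher. Such a loss and a change of expression within the neural cells cannot be told apart, because no sample holds the fresh isolate without other cells.

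Recounting calls over other splits argues against chance for LT-HSC against KSL-B6, where of 35 splits the real one alone gave as many (78, highest other 14). This share of 1 in 35 is the smallest the test can give, and it is not adjusted for the other comparisons recounted. For LT-HSC against MLL-LSC the real split of 35 alone gave as many too (66, highest other 7). There the numbers pair the samples by their correlations, and the 8 splits that part the 3 pairs (highest other 3) are too few to give a share under 0.05. For the tissues 1 of 100 splits of single samples each gave as many, with 105 for blood (highest other 15), 86 for muscle (28) and 105 for neural cells (11), but these break up the populations. With whole populations regrouped, 10 of 100 splits gave as many for blood (highest other 117), 74 for muscle (117) and 8 for neural cells (110), so chance is not excluded for the tissues. The 10 splits of 3 against 3 are too few as well. There the real counts and highest others were 59 and 0 for NSPC-P0 against NSPC-P0-Exp, 54 and 0 for NSPC-P0-Exp against NSPC-Adult, 70 and 0 for the MLL cells, and 88 and 1 for KSL-ETO.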
